A study of Homo sapiens with 46 samples.

How the data were processed

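RNA was sequenced in 40 libraries and H3K4me3 chromatin in 6. RNA was extracted with Trizol and made into libraries with a TruSeq Stranded Total RNA kit, per the labels' protocols, which give no kit for 1 ZNF441 KO library. Reads were trimmed with Trimmomatic 0.36, aligned to hg19 with HISAT2 and counted with featureCounts, and the authors used DESeq2, per the submitters' processing notes. The deposited tables hold whole-number counts per gene. The annotation, the strand setting and the handling of reads that align to several places are not stated, so values of pseudogenes, near-identical genes and overlapping antisense transcripts are uncertain. Chromatin reads were trimmed with Trimmomatic 0.36, aligned with Bowtie2, handled with SAMtools and bedtools and called as peaks with MACS2 2.1.1.20160309, per the submitters' processing notes. For each peak the deposited files give a score, a ratio of signal over background at the summit (fold enrichment), a −log10 p-value and a −log10 q-value. These were used only to filter or describe peaks within a list.

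Samples were grouped by title. For the ZNF468 knockout the genotype label and treatment text name ZNF441, and the counts of both genes go with the titles. Each count table had 57820 genes, of which 51996 had a symbol in the given table and 932 shared a symbol with another. Total counts per library ranged from 2079781 to 15546114. A count of 0 was read as an upper limit of 3 counts over the group when giving a fold, and for genes with 1 to 3 counts in a group a ratio with a 95% counting interval is given.

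Each comparison was fitted on its own libraries in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, two-sided, TMM factors, filterByExpr with a minimum of 10 counts and a total of 15, prior count 2). P values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The comparisons were ZNF519 KO against WT in hESC, at day 14 and at day 35, ZNF519 OE against control, ZNF441 KO and ZNF468 KO against WT, and WT organoids of day 35 against day 14. A pair of interaction contrasts over all 18 libraries of the ZNF519 table compared the knockout effect at day 35 with that at day 14 and in hESC. The biological coefficient of variation was 0.295 in hESC, 0.046 at day 14, 0.041 at day 35, 0.185 in HEK293, 0.102 for ZNF441 and 0.113 for ZNF468. Called genes were compared between comparisons without common libraries by Fisher's exact test (two-sided, adjusted over the pairs).

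The 25 gene lists covered markers of pluripotent cells, neural progenitors, telencephalic and cortical identity, neurons, ventral forebrain and inhibitory neurons, midbrain, hindbrain and spinal cord, cortical hem and choroid plexus, retina and pigment cells, neural crest and mesenchyme, endoderm and mesoderm, surface epithelium, and endothelial and blood cells. They also covered cell cycle, p53 targets, hypoxia and glycolysis, the unfolded protein and integrated stress response (stress response below), interferon response and antigen presentation, imprinted genes, beta protocadherins, genes at 20q11.21, the KRAB zinc finger clusters at 19p12, 19p13.2 and 19q13.41, WNT signalling and cholesterol synthesis. Lists with at least 3 tested members were tested with limma 3.58.1 camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The endothelial and blood list never had 3 tested members. The lists, comparisons, tests and alternatives, other than those named below as added, were fixed before the data were examined.

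Genes were named by a fixed rule. It took the targeted gene, the 6 largest rises and falls among genes with a symbol, at least 2 CPM and groups that did not overlap, the 3 smallest p values in each direction, up to 3 called members per list (or 2 abundant members where none passed) and 4 genes per direction of an interaction. Groups do not overlap by chance in 10% of genes with 3 against 3 libraries and in 2.86% with 4 against 4. Shared genes named in the overlaps, and immediate early genes outside day 35, are exceptions chosen after their values were seen.

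Whether equal replicate numbers pair libraries was checked by correlating deviations from the group means. For ZNF468 the correlations were 0.292, 0.165, 0.297 and 0.151, all over 0.1. The numbers were therefore treated as possible pairs, from the data and not from the labels. KO replicates 2 and 4 correlated best with a WT library of another number, so pairing by number is not established. Alternatives were DESeq2 1.42.0 as test and as scaling, no filter on low counts, a mean of at least 2 CPM, a threshold of 0.01, a replicate block, a joint fit of all 18 libraries and leaving out each library in turn. Added after seeing the data were the ZNF468 fit with replicates 1 and 2 against 3 and 4 as a block, and the HEK293 fit without control replicate 2 and OE replicate 3. The pipeline was tested on simulated data, where 88.1% of 2-fold changes were recovered at day 14, 86.6% at day 35, 89.6% for ZNF441 and 88.1% for ZNF468. Of the simulated calls, 7.8% at day 14, 6.6% at day 35, 7.9% for ZNF441 and 10.1% for ZNF468 were false.

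Peaks of the 6 chromatin libraries were merged with bedtools 2.31.1 (overlap of at least 1 bp) and regions were counted by the libraries with a peak in them. Alternatives were a −log10 q of at least 5, equal numbers of peaks per library, merging within 500 bp and coverage of at least 0.5 of the region. Per-library measures were compared by exact permutation (two-sided). The planned test of H3K4me3 regions against RNA was not run, since it needs an hg19 annotation, which was not used here. Gene order along chromosomes was taken from GRCh38 annotation for neighbours only. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.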

Results

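The data comprise 46 libraries made to ask what primate-specific KRAB zinc finger proteins, DNA-binding repressors of recent evolutionary origin, do in human cells. RNA sequencing covered 40 libraries and chromatin immunoprecipitation of H3K4me3, a histone mark of active promoters, covered 6. ZNF519 was deleted with CRISPR/Cas9 in H9 human embryonic stem cells (hESC), and RNA was read from undifferentiated cells and from cortical organoids, which are cell aggregates grown toward cerebral cortex, at day 14 and day 35. Each of these 3 stages has 3 wild-type (WT, empty vector) and 3 knockout (KO) libraries. In hESC the 3 libraries of a group are different clones (WT clones 2, 6 and 7, KO clones 31, 92 and 93), while all organoids came from WT clone 7 and KO clone 31. ZNF441 was deleted in organoids of day 35 and ZNF468 in organoids of day 5, with 4 WT and 4 KO libraries each. Titles of these libraries name no clone, so each group may hold samples of a single clone, and a difference of clones cannot be told from the deletion. ZNF519 was also overexpressed (OE) in HEK293, a human embryonic kidney line, with 3 OE and 3 control libraries. H3K4me3 was mapped in 3 WT and 3 ZNF519 KO libraries of day 35 organoids. Total counts ranged from 10068004 to 13400362 per library in hESC, from 9839310 to 13175162 at day 14 and from 11761251 to 15546114 at day 35. They ranged from 2079781 (OE replicate 3) to 7674804 in HEK293, from 7493583 to 10748043 in the ZNF441 organoids and from 6514686 to 12157022 in the ZNF468 organoids. Expression below is in TMM-scaled CPM (counts relative to library size), as mean ± SD, scaled within each comparison, and fold changes are log2 ± SE from edgeR.

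The targeted genes were read in every library first. ZNF519 had 491, 107 and 489 counts in WT hESC clones 2, 6 and 7, and 5, 67 and 17 counts in KO clones 31, 92 and 93. In organoids, ZNF519 had 620 to 756 counts in the WT libraries of day 14 and 321 to 486 in those of day 35, and 0 counts in all 6 KO libraries, which allows at most 0.272 CPM in any of them. HEK293 controls had 168, 235 and 245 ZNF519 counts, and OE libraries had 47712, 48843 and 14116. ZNF441 had 360 to 462 counts in the WT libraries and 0 in each of the 4 KO libraries. ZNF468 had 128, 115, 201 and 140 counts in the WT libraries and 3, 0, 1 and 2 in the KO libraries. The genotype label of the ZNF468 KO libraries names ZNF441 where their titles name ZNF468. ZNF441 in those libraries was 7.80 ± 1.46 CPM against 8.87 ± 1.82 in WT (SD, n = 4), so the groups follow the titles.

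**Figure D1:**
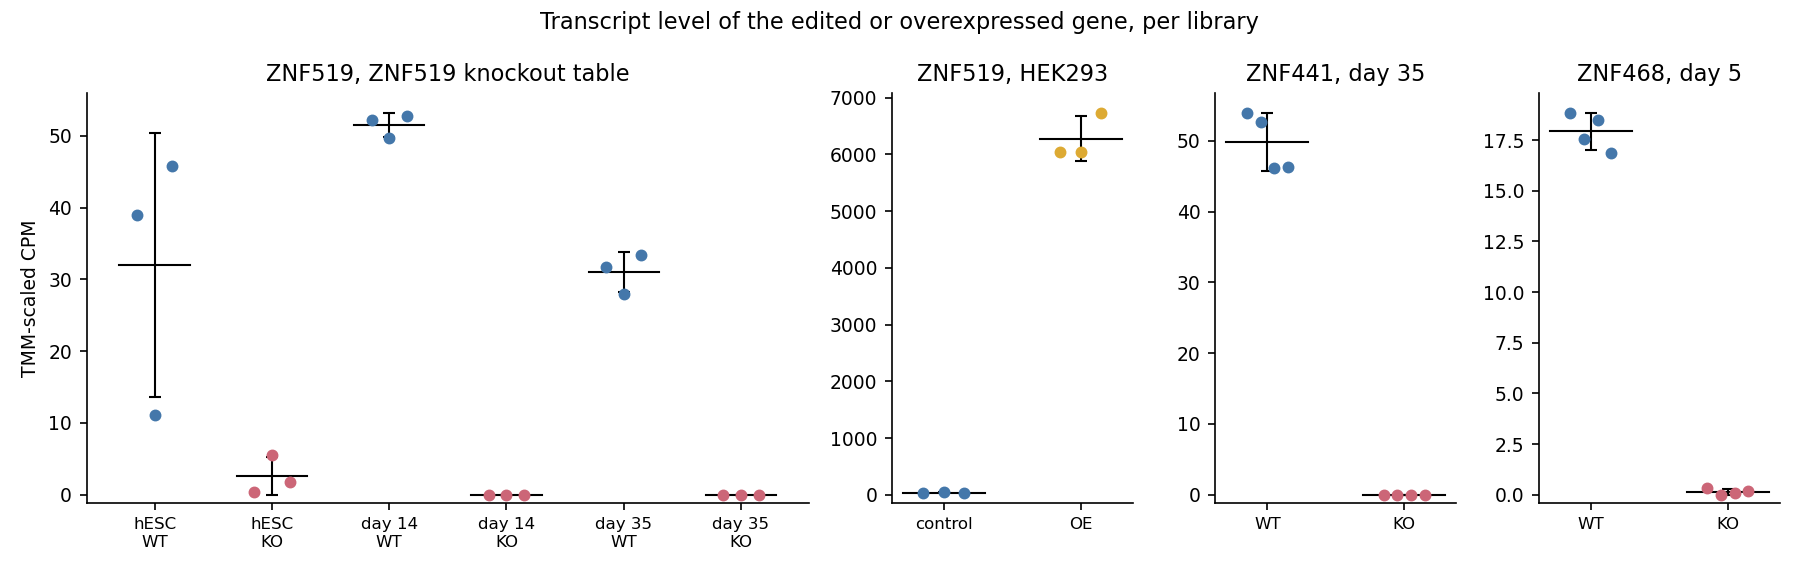
Level of the edited or overexpressed gene in each library, in TMM-scaled CPM (scaled over each count table) on linear axes that differ between panels; points are libraries, horizontal lines the group mean and bars the SD, with WT and control in blue, KO in red and OE in yellow. ZNF519 is at 0 in all KO organoids, whereas hESC KO clone 92 is at 5.54 CPM and WT clone 6 at 11.1 CPM.

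Comparing WT organoids of day 35 with those of day 14 shows what these organoids were made of. Between the 2 ages they lost pluripotency and cell cycle transcripts and gained transcripts of neurons, with 6786 genes higher and 6794 lower of 17635 tested. GRIN2B, an NMDA receptor subunit, went from 0.983 ± 0.266 to 845 ± 35.8 CPM (n = 3 per age), and BCL11B, a transcription factor of deep-layer cortical neurons, from 3.86 ± 0.769 to 857 ± 54.9 CPM. LIN28A, a pluripotency RNA-binding protein, fell from 194 ± 10.5 to 0.369 ± 0.318 CPM, and SALL4 from 186 ± 11.6 to 0.987 ± 0.233 CPM. Of the neuron markers 17 rose and 7 fell among 25 tested. DCX rose by 2.15 ± 0.03 and MYT1L by 4.40 ± 0.05 on the log2 scale. Of the ventral forebrain and inhibitory neuron markers 9 of 11 rose and 2 fell, with GAD1 up 2.76 ± 0.05 and DLX6 up 3.50 ± 0.07. The pluripotency list fell in 10 of 11 members and the cell cycle list in 29 of 30, including MCM2 (−2.06 ± 0.06) and MCM5 (−2.20 ± 0.06), which license DNA replication. Neural progenitor markers fell in 20 of 24 and rose in 4, among them TNC, an outer radial glia gene, up 4.73 ± 0.09. Telencephalic and cortical identity genes fell in 17 of 20 and rose in 1, with FEZF1 at −4.02 ± 0.08 and LHX2 at −2.70 ± 0.05. Genes of cholesterol synthesis rose in 21 of 22 and fell in 1 (HMGCS1 up 2.29 ± 0.04), hypoxia and glycolysis genes rose in 20 of 22 and fell in 1, and beta protocadherins rose in 14 of 15 and fell in 1. Of the interferon and antigen presentation list 15 of 19 fell and 3 rose, although IFI44L and IFI44, both interferon-induced, went from 0 counts to 6.78 ± 1.85 and 6.36 ± 1.94 CPM, at least 84.2-fold and 78.7-fold higher. Members also moved in both directions in the lists of cortical hem and choroid plexus (2 rose and 7 fell of 11), neural crest and mesenchyme (4 and 6 of 11), imprinted genes (13 and 11 of 25), p53 targets (7 and 10 of 23), WNT signalling (4 and 10 of 15) and genes at 20q11.21 (8 and 4 of 16), a segment often amplified in cultured hESC. Of the 3 families of KRAB zinc finger genes on chromosome 19, 9 rose and 14 fell of 25 in the 19p12 cluster, 14 rose and 3 fell of 23 in 19p13.2, and 15 rose and 11 fell of 34 in 19q13.41. ZNF519 fell from 55.1 ± 1.94 to 32.6 ± 2.89 CPM (−0.75 ± 0.06) and ZNF441 rose from 13.0 ± 0.450 to 53.6 ± 2.96 CPM (2.05 ± 0.07). Every fold change named here had an edgeR adjusted p of 4.6e-09 or less, and the counts per list were the same when adjusted over the list alone. The limma camera test called cholesterol synthesis (adjusted p = 6.3e-07), cell cycle (1.7e-08), neurons (0.00482) and pluripotent cells (0.000152), and with an estimated correlation these had adjusted p = 0.329, 0.369, 0.369 and 0.305. It also called hypoxia (adjusted p = 1.9e-05), telencephalic markers (0.000412) and interferon genes (0.0162), each at adjusted p = 0.369 with an estimated correlation. Beta protocadherins (0.000276) and ventral forebrain markers (0.00565) were called too, both at adjusted p = 0.329 with an estimated correlation, and progenitors (0.00161) at adjusted p = 0.428 with an estimated correlation. All 6 libraries came from a single clone.

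In undifferentiated hESC, no gene differed between the ZNF519 KO and WT clones by the edgeR test. ZNF519 itself averaged 2.37 ± 2.42 CPM in KO clones and 29.4 ± 16.8 in WT clones (n = 3 each), a log2 difference of −3.61 ± 0.87 with an adjusted p of 0.734. Pluripotency genes were abundant in both groups, with LIN28A at 2021 ± 41.1 CPM in KO and 2613 ± 704 in WT and DNMT3B, a DNA methyltransferase, at 2155 ± 163 and 2345 ± 478. Markers of neural progenitors (NES 601 ± 19.9 against 1243 ± 1069 CPM), of mesenchyme (TAGLN 456 ± 58.9 against 868 ± 610) and of surface epithelium (KRT8 178 ± 16.1 against 273 ± 148) varied mainly among the WT clones. None of the members of the 22 lists tested passed, over all genes or adjusted over the list alone. Camera still placed the 19p12 and 19q13.41 KRAB zinc finger clusters higher (median log2 0.47 and 0.33, both adjusted p = 1.2e-05) and stress response genes lower (median −0.40, adjusted p = 0.00326), each at adjusted p = 0.816 with an estimated correlation. It also placed progenitor markers and WNT genes (both adjusted p = 0.0259) and genes at 20q11.21 (adjusted p = 0.0261) lower, again at adjusted p = 0.816 with an estimated correlation. KDR, an endothelial receptor also made by hESC, was at 79.4 ± 3.82 CPM in KO and 76.3 ± 2.40 in WT. At an unadjusted p under 0.05 there were 294 genes, and DESeq2 called 8. WT clone 6 stood apart, with 0.396% mitochondrial counts against 3.82% to 5.30% in the other 5 clones and a TMM factor of 0.802 against 0.941 to 0.952, and without it (WT replicate 2) edgeR called 14 genes, 7 in each direction. In simulated data for this comparison 59.1% of 4-fold changes and 0 of 67 changes of 2-fold were recovered, so moderate effects were not detectable here. The simulation drew each gene independently, without a shift of many genes in 1 clone, so it may overstate recovery. Large effects could be missed too, as ZNF519 itself did not pass. No paired analysis was possible because the replicate numbers name different clones.

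At day 14, 11 of 25 KRAB zinc finger genes of the 19p12 cluster were lower in ZNF519 KO organoids, as were 4 of 24 neuron markers, and 3 of 12 neural crest and mesenchyme markers were higher. The largest falls beside ZNF519 were FAR2P1, POTEF and MED15P9, neighbours on chromosome 2 of which FAR2P1 and MED15P9 are pseudogenes and POTEF belongs to a family of near-identical genes. FAR2P1 went from 38.0 ± 4.46 CPM in WT to 0.256 ± 0.292 in KO (n = 3 each, −7.11 ± 0.24, adjusted p = 1.9e-14) and POTEF from 32.1 ± 2.87 to 0.321 ± 0.293 (−6.56 ± 0.23, adjusted p = 2.7e-14). MED15P9 had a KO to WT ratio of 0.00403 (95% counting interval 0.000102 to 0.0226). ZNF519 was at 59.4 ± 2.17 CPM in WT and 0 in KO, at least 602.5-fold lower. In the 19p12 cluster 11 genes fell and none rose (13 fell when adjusted over the list alone), among them ZNF737 (−1.95 ± 0.19), ZNF253 (−0.69 ± 0.08) and ZNF85 (−0.67 ± 0.07). The camera test placed that list lower (adjusted p = 7.4e-09), and adjusted p = 0.203 with an estimated correlation. Elsewhere on chromosome 19 the zinc finger genes ZFP28 (−4.39 ± 0.30) and ZNF132 (−4.25 ± 0.36) fell. Of the 24 neuron markers 4 fell and none rose (10 fell adjusted over the list alone), with ELAVL4, a neuronal RNA-binding protein, at −0.45 ± 0.06 and RELN, made by the first cortical neurons, at −0.52 ± 0.09. Camera gave an adjusted p of 0.000845, and adjusted p = 0.481 with an estimated correlation. Of the 12 neural crest and mesenchyme markers 3 rose and none fell (6 rose adjusted over the list alone), led by the smooth muscle gene TAGLN at 1.32 ± 0.10. The other 2 calls were lost without single libraries, ACTA2 without WT replicate 3 (adjusted p = 0.0689) and COL1A1 without WT replicate 2 (adjusted p = 0.0555), as was the neuron marker TBR1 without WT replicate 2 (adjusted p = 0.111). In the camera test the adjusted p was 1.7e-05, and adjusted p = 0.164 with an estimated correlation. CNN1, another smooth muscle gene, rose by 1.87 ± 0.24, and THBS1, a matrix protein, by 1.12 ± 0.08. WLS, which exports WNT proteins, rose by 1.67 ± 0.20 from 8.01 ± 2.27 to 25.1 ± 8.69 CPM, and in its list 1 rose and 1 fell of 15 (3 and 1 adjusted over the list alone).

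Other groups at day 14 were mixed. Of 20 telencephalic genes 3 rose and 2 fell, and those that rose were FGFR3 (0.84 ± 0.09), NR2F1 (0.62 ± 0.08) and NR2F2 (0.73 ± 0.10), the last pair being transcription factors of the caudal cortex. Of the 11 hem and choroid plexus markers 1 rose (KCNJ13, 0.84 ± 0.15) and 3 fell (RSPO1 by −0.93 ± 0.15). Of the 11 pluripotency markers 3 rose and 1 fell, and LIN28A went from 209 ± 10.9 to 274 ± 6.10 CPM. Of 23 imprinted genes 1 rose and 3 fell, the largest of these falls being NLRP2, from 41.6 ± 4.68 to 8.33 ± 1.38 CPM. Stress response genes rose in 4 of 24 (8 rose and 1 fell adjusted over the list alone), including the chaperone HSPA5 (0.29 ± 0.05), with a camera adjusted p of 0.00235, and adjusted p = 0.293 with an estimated correlation. Outside the chosen lists the protocadherin PCDHGC3 rose from 22.7 ± 0.176 to 46.0 ± 1.27 CPM and INPP5F, a phosphoinositide phosphatase, from 57.9 ± 5.71 to 123 ± 8.01. No gene of the cell cycle (30 tested), cholesterol synthesis (22), beta protocadherin (14), surface epithelium (5), 20q11.21 (16), 19p13.2 (23) or 19q13.41 (35) lists passed over all genes. Of 23 progenitor markers 2 rose (VIM, 0.32 ± 0.04) and 1 fell, of 23 hypoxia genes 2 rose, of 16 interferon genes 2 rose and of 5 retina and pigment markers 1 fell (DCT, −0.58 ± 0.07). Of 3 midbrain and hindbrain markers none passed. Ventral forebrain markers fell in 1 of 10 (4 adjusted over the list alone), with a camera adjusted p of 0.00288, and adjusted p = 0.203 with an estimated correlation. Without 1 library the adjusted p reached 0.173 for CALR and 0.219 for ATF4, 2 of the 4 stress response genes that rose, and 0.207 for CDH2 and 0.1299 for ZIC1 (progenitors). It reached 0.0864 for PEG10 (imprinted), 0.0839 for HTR2C (hem) and 0.118 for DKK3 (WNT). Leaving out 1 library gave an adjusted p of up to 0.157 for GAD1 (the ventral marker that fell), 0.0797 for SLC2A3 and 0.157 for ALDOA (hypoxia), and 0.110 for IFITM3 and 0.0999 for B2M (interferon). In p53 targets 1 of 23 rose (SESN2, adjusted p of up to 0.169 without 1 library), with a camera adjusted p of 0.00652, and adjusted p = 0.279 with an estimated correlation. Of the lists with no member past, camera called cholesterol synthesis (adjusted p = 0.00294, and adjusted p = 0.403 with an estimated correlation) and beta protocadherins (adjusted p = 0.000326, and adjusted p = 0.208 with an estimated correlation). In all, 349 genes were higher and 282 lower of 16885 tested, 98 of them by at least 2-fold. Clone and genotype are the same split of these 6 libraries, and the count fell to 378, 323 or 367 without WT replicate 1, 2 or 3. It was 40 when all 18 libraries of the table shared a dispersion estimate, 368 with DESeq2, 311 at an adjusted p of 0.01 and 997 with a term for replicate number.

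At day 35, the largest rises in ZNF519 KO organoids included NPAS4, FOS, FOSB and NR4A1, known as immediate early genes, and 16 of 22 genes of cholesterol synthesis rose slightly. No list of immediate early genes was fixed or tested, and the rapidly induced genes ATF3 (0.41 ± 0.19, adjusted p = 0.190) and DUSP1 (0.12 ± 0.07, adjusted p = 0.2999) did not pass. NPAS4, an activity-dependent transcription factor of neurons, went from 2.71 ± 0.0824 CPM in WT to 44.0 ± 3.53 in KO (n = 3 each, 4.01 ± 0.10, adjusted p = 5.7e-14). FOS went from 8.12 ± 1.34 to 58.9 ± 3.47 CPM (2.86 ± 0.09, adjusted p = 5.6e-13), and FOSB rose by 2.92 ± 0.26, NR4A1 by 1.93 ± 0.09 and NR4A3 by 1.78 ± 0.08. Of the cholesterol synthesis list none fell (17 rose adjusted over the list alone). Among them IDI1 rose by 0.33 ± 0.03 and INSIG1 by 0.29 ± 0.04. The camera adjusted p of this list was 7.8e-11, and adjusted p = 0.218 with an estimated correlation. Of 30 cell cycle genes 7 rose and 1 fell (10 and 1 adjusted over the list alone), with TOP2A up 0.26 ± 0.05. For this list camera returned an adjusted p of 0.00862, and adjusted p = 0.669 with an estimated correlation. Stress response genes rose in 3 of 24 (5 adjusted over the list alone), with DDIT4 up 0.35 ± 0.04 and ASNS, which makes asparagine, up 0.21 ± 0.04. By camera the list had an adjusted p of 0.00242, and adjusted p = 0.257 with an estimated correlation. Of 23 hypoxia and glycolysis genes 3 rose and none fell, SLC2A3 by 0.46 ± 0.05 and PFKFB3 by 0.41 ± 0.06. Without 1 library the adjusted p reached 0.148 for MXI1 (hypoxia), 0.112 for SHMT2 (stress response) and 0.0620 and 0.0557 for CENPF and CCND1 (cell cycle). The list had a camera adjusted p of 0.0367, and adjusted p = 0.669 with an estimated correlation.

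The largest falls at day 35 included the chromosome 2 neighbours and several zinc finger genes. FAR2P1 was at 32.8 ± 3.20 CPM in WT and 0.244 ± 0.153 in KO (−6.94 ± 0.20, adjusted p = 1.8e-13), and POTEF at 30.9 ± 1.64 and 0.179 ± 0.0140 (−7.35 ± 0.18, adjusted p = 2.7e-14). MED15P9 had a ratio of 0.00399 (95% counting interval 0.000101 to 0.0225). ZNF519 was at least 385.1-fold lower in KO, and the pseudogene ZNF542P, at 10.4 ± 0.566 CPM in WT, had no count in KO and was at least 134.4-fold lower. ZFP28 fell by 5.23 ± 0.19 from 20.7 ± 2.06 CPM, and the long noncoding RNA CCDC144NL-AS1 fell by 3.79 ± 0.12 from 31.6 ± 1.42 CPM. In the 19p12 cluster 9 of 25 genes fell and none rose (11 fell adjusted over the list alone), with ZNF737 at −1.28 ± 0.10 and ZNF682 at −0.47 ± 0.08. Camera gave an adjusted p of 0.00242, and adjusted p = 0.257 with an estimated correlation. In the beta protocadherins 3 of 14 fell and none rose (5 fell adjusted over the list alone), PCDHB4 by 0.52 ± 0.10 on the log2 scale. For this list camera returned an adjusted p of 0.00228, and adjusted p = 0.218 with an estimated correlation. Neuron markers moved both ways, with 3 up and 2 down of 21 (SNAP25 0.22 ± 0.04, CNTN2 −0.27 ± 0.05), as did progenitor markers with 2 up and 4 down of 24 (SOX1 0.28 ± 0.04). Of 10 ventral forebrain and inhibitory neuron markers 3 rose and none fell, SST, a neuropeptide of interneurons, going from 44.5 ± 3.86 to 70.8 ± 4.20 CPM. Imprinted genes rose in 3 (PEG10 0.32 ± 0.04, ZDBF2 0.34 ± 0.04) and fell in 6 (NLRP2 −1.07 ± 0.09) of 22. Of 14 WNT genes 2 fell, LEF1 by 1.01 ± 0.18 on the log2 scale, and of 16 genes at 20q11.21 2 rose (KIF3B, 0.19 ± 0.03) and 3 fell (DNMT3B, −0.55 ± 0.08). Pluripotency markers fell in 1 of 7, telencephalic markers in 2 of 16, hem and choroid plexus markers in 1 of 7, p53 targets in 1 of 23 and interferon genes in 2 of 18, with none up. Neural crest and mesenchyme markers rose in 1 and fell in 2 of 7. The 19q13.41 cluster had 2 up and 1 down of 32, and the 19p13.2 cluster 1 down of 23 (none adjusted over the list alone). None passed among 3 retina and pigment markers or 3 endoderm and mesoderm markers (1 of the latter rose adjusted over the list alone). Leaving out 1 library gave an adjusted p of up to 0.132 for ISL1 and 0.144 for DLX6 (ventral forebrain), 0.113 for PCDHB3 and 0.193 for PCDHB12, 0.115 for OTX2 and 0.1665 for SP8 (the telencephalic falls, SP8 also being a WNT gene) and 0.0854 for WNT2B (hem). For LIX1 and FABP7 (progenitors) it gave up to 0.0901 and 0.0522, for MAP2 (neurons) 0.105 and for TPX2 (20q11.21 and cell cycle) 0.0902. It gave up to 0.0553 for DDB2 (p53), 0.0681 for IRF9 and 0.0775 for IFI27 (interferon), 0.171 for PRRX1, 0.105 for POSTN and 0.134 for PDGFRB (mesenchyme), 0.0932 for ZNF320, 0.143 for ZNF880 and 0.0627 for ZNF665 (19q13.41) and 0.1815 for ZNF69 (19p13.2). The neuron list had a median of −0.031 while camera pointed up (adjusted p = 0.893). In all, 818 genes were higher and 631 lower of 16566 tested, 106 of them by at least 2-fold. Clone and genotype are the same split here too, and the count fell to 813, 667 or 684 without KO replicate 1, 2 or 3. It was 48 when all 18 libraries shared a dispersion estimate, 733 with DESeq2 and 593 at an adjusted p of 0.01.

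**Figure D2:**
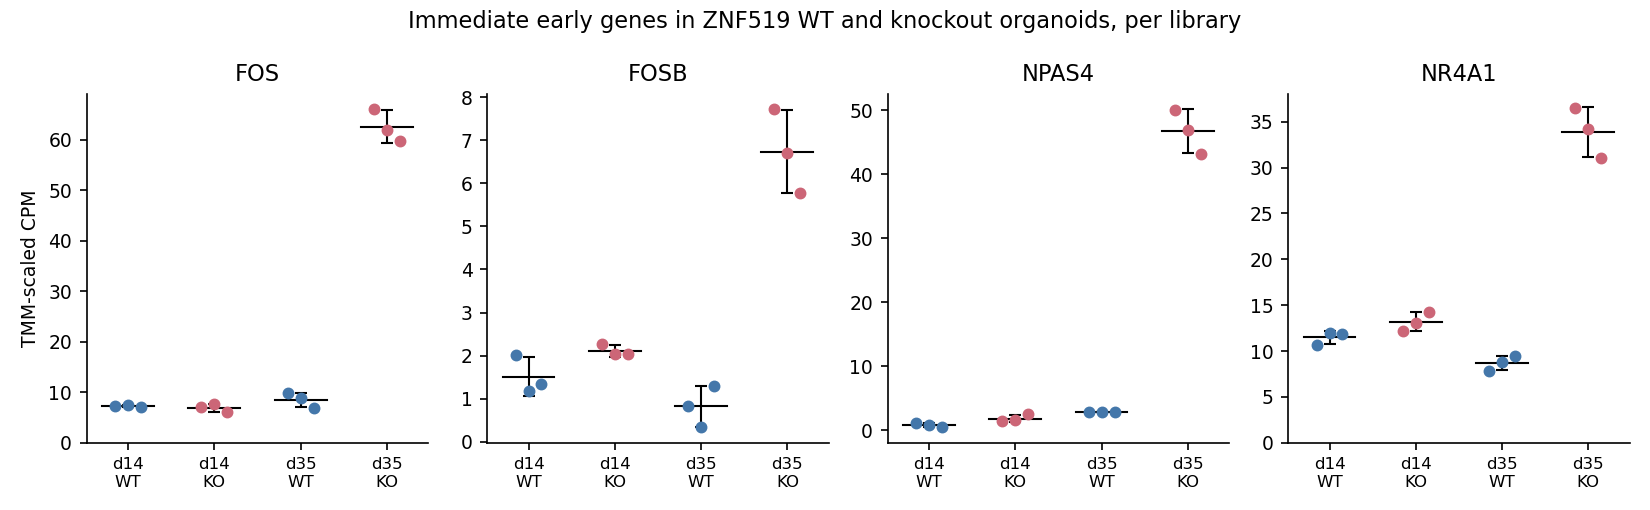
Levels of 4 immediate early genes in WT (blue) and ZNF519 KO (red) organoids of day 14 and day 35, in TMM-scaled CPM (scaled over the whole table) on linear axes that differ between panels; points are libraries, lines the mean and bars the SD of 3 libraries. At day 35 all KO points lie above all WT points, with FOS at 62.6 ± 3.27 CPM in KO on this scale.

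The difference between KO and WT was compared across stages as an interaction over all 18 libraries. Organoids of both ages hold WT clone 7 and KO clone 31 alone and hESC hold 3 clones per genotype, so stage and clones change together in the contrast with hESC. FOS had the clearest difference between day 35 and day 14. The KO effect on FOS was larger at day 35 by 2.95 ± 0.20 (adjusted p = 9.9e-07) and that on NPAS4 by 2.95 ± 0.42 (adjusted p = 0.0239), while NR4A1 differed by 1.76 ± 0.27 and SLC7A8, an amino acid transporter, by 1.198 ± 0.18 (both adjusted p = 0.0245). In all 6 genes passed, all with the larger value at day 35, of 19579 tested. In simulated data 10.4% of 2-fold differences were recovered in this contrast and 11.9% in that with hESC. Of 4-fold differences 66.7% were recovered in each, so few calls do not mean that the effect hardly differed. Between day 35 and hESC 19 genes passed, 10 with a higher and 9 with a lower effect at day 35. FOS (3.17 ± 0.20, adjusted p = 3.9e-07), SLC7A8 (1.48 ± 0.16), NR4A1 (2.31 ± 0.27) and FOSB (3.78 ± 0.47) were among the former, and ZFP28 (−5.56 ± 0.90), ZNF772 (−4.62 ± 0.70), ZNF132 (−4.52 ± 0.72) and HHLA1 (−3.55 ± 0.61) among the latter. In hESC, clone 31 was already below clone 7 for ZFP28 (0.244 and 3.89 CPM), ZNF132 (0.896 and 5.01) and ZNF772 (2.20 and 6.39), so for these 3 genes the contrast cannot be read as one of stage. HHLA1 was higher in clone 31 than in clone 7 there (43.3 and 16.6 CPM). No list member passed in the comparison with day 14. There camera placed telencephalic markers (adjusted p = 0.00482) and neural crest and mesenchyme markers (adjusted p = 0.00565) lower and ventral forebrain markers higher (adjusted p = 0.0481), each at adjusted p = 0.158 with an estimated correlation. It placed p53 targets lower (adjusted p = 0.0481, and adjusted p = 0.215 with an estimated correlation). In the comparison with hESC 1 interferon gene fell. For the contrast with hESC, camera placed stress response genes (adjusted p = 1.6e-05, and adjusted p = 0.312 with an estimated correlation), cholesterol genes (adjusted p = 0.00790, and adjusted p = 0.312 with an estimated correlation) and hypoxia genes (adjusted p = 0.0242, and adjusted p = 0.405 with an estimated correlation) higher. It placed the 19q13.41 cluster (adjusted p = 0.000198, and adjusted p = 0.580 with an estimated correlation) and the 19p12 cluster lower (adjusted p = 3.3e-06, and adjusted p = 0.454 with an estimated correlation). Single libraries decided most of these calls. FOS passed in both contrasts whichever library was left out. Against day 14, leaving out 1 library gave an adjusted p of up to 0.183 for NPAS4, 0.148 for NR4A1 and 0.148 for SLC7A8. Against hESC it gave up to 0.163 for HHLA1, 0.111 for ZFP28, 0.108 for ZNF132 and 0.0746 for ZNF772. The count against day 14 was 130 without hESC WT replicate 2, 1 to 3 without any single library of day 14 or day 35 and 1 without hESC KO replicate 3, and it was 423 on the 12 organoid libraries with a term for replicate number. The count against hESC was 477, 32 and 75 without hESC WT replicates 2, 1 and 3, it was 35, 8 and 9 without hESC KO replicates 1, 2 and 3, and 6 to 11 without any single library of day 35.

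Overexpression of ZNF519 in HEK293 raised ZNF519 from 36.0 ± 5.79 to 6274 ± 400.3 CPM (n = 3 each, 7.45 ± 0.28, adjusted p = 4.8e-06), and no other gene passed the edgeR test among 14632. Of the 19p12 cluster, of which members fell in KO organoids, no gene of 27 passed, and ZNF91 was at 87.9 ± 6.05 CPM in OE and 89.1 ± 3.06 in controls (adjusted p = 0.985). FOS was at 6.12 ± 1.67 CPM in OE and 8.08 ± 0.478 in controls, and NPAS4 had no count in any of the 6 libraries. Genes of cholesterol synthesis had a median of −0.23 with no member past of 21, over all genes or adjusted over the list alone. Camera placed the list lower (adjusted p = 0.0220, and adjusted p = 0.515 with an estimated correlation). In the other 22 lists no member passed and camera made no call (1 stress response gene rose adjusted over the list alone). At an unadjusted p under 0.05 there were 947 genes, DESeq2 called 14 (2 higher and 12 lower), and 93.9% of simulated 4-fold and 58.2% of 2-fold changes were recovered at this depth. Control replicate 2 differed from the other controls (TMM factor 0.862 against 1.00 and 1.04) and OE replicate 3 had the fewest counts. The count was 33 without control replicate 2, 20 without both of these libraries, an alternative chosen after seeing the data, and 116 with no filter on low counts.

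In ZNF441 KO organoids of day 35 few genes beside ZNF441 differed from WT, several of them going from near 0 to clearly present or the reverse. ZNF441 was at 49.8 ± 4.12 CPM in WT and 0 in KO (n = 4 each), at least 618.4-fold lower. Among the losses, CYP2R1, a vitamin D 25-hydroxylase, had a KO to WT ratio of 0.00693 (95% counting interval 0.00142 to 0.0204) and ZNF726 one of 0.0139 (0.00166 to 0.0512). ZNF585B fell from 22.4 ± 2.74 to 0.398 ± 0.111 CPM (−5.75 ± 0.21, adjusted p = 3.3e-11), ZNF772 changed by −3.14 ± 0.15 and PPP1R3C, a glycogen-targeting phosphatase subunit, by −2.36 ± 0.29. ZNF680 fell from 26.7 ± 1.72 to 12.1 ± 1.74 CPM. Among the gains, CAT, which encodes catalase, had no count in WT and 6.66 ± 1.67 CPM in KO, at least 69.6-fold higher. ZNF596 had a ratio of 119 (95% counting interval 32.7 to 991), and CHCHD2, a mitochondrial protein gene, doubled from 45.4 ± 2.36 to 89.9 ± 9.71 CPM (0.99 ± 0.09, adjusted p = 9.5e-06). FOS rose from 19.8 ± 2.16 to 38.0 ± 8.13 CPM (0.95 ± 0.14, adjusted p = 0.00269). NPAS4 (6.61 ± 0.748 to 13.15 ± 3.98 CPM, adjusted p = 0.0410) passed with all 8 libraries and without KO replicate 1 or 2. For NPAS4 the adjusted p was 0.0987 and 0.0867 without KO replicates 3 and 4, and 0.208, 0.167, 0.0781 and 0.122 without WT replicates 1, 2, 3 and 4. No member passed in the lists of neurons (DCX 2600 ± 327 against 2775 ± 238 CPM), progenitors (VIM 568 ± 56.0 against 606 ± 45.7), telencephalon, cholesterol synthesis or cell cycle (TOP2A 237 ± 54.3 against 252 ± 16.2). Of the 3 zinc finger clusters, 2 of 27 genes fell in 19p12 and 1 of 23 in 19p13.2, this being ZNF441 itself. One of the falls in 19p12, ZNF737, was lost without KO replicate 3 or 4 or WT replicate 1, 2 or 3 (adjusted p of 0.0984, 0.107, 0.125, 0.153 and 0.0781). Camera called the p53 targets higher with no member past (adjusted p = 0.00242, and adjusted p = 0.340 with an estimated correlation). When adjusted over the list alone 2 of 21 rose. Camera also placed the 19p12 cluster lower (adjusted p = 0.00230, and adjusted p = 0.691 with an estimated correlation). Stress response genes (adjusted p = 0.00885, and adjusted p = 0.341 with an estimated correlation), endoderm and mesoderm markers (adjusted p = 0.0247, and adjusted p = 0.341 with an estimated correlation, 2 of 3 up adjusted over the list alone) and hypoxia genes (adjusted p = 0.0309, and adjusted p = 0.802 with an estimated correlation) were placed higher, with no member past. In all, 12 genes were higher and 17 lower of 15040 tested. DESeq2 called 45, a term for replicate number gave 50, and with no filter on low counts there were 155.

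ZNF468 KO organoids of day 5 were marked by losses and gains in neighbouring genes. ZNF468 fell from 17.9 ± 0.917 to 0.145 ± 0.137 CPM (n = 4 each, −6.84 ± 0.28, adjusted p = 2.0e-08) and ZNF28, its neighbour in the 19q13.41 cluster, from 29.2 ± 2.75 to 0.115 ± 0.102 (−7.78 ± 0.26, adjusted p = 2.2e-09). In that cluster 4 of 35 genes fell and 2 rose (5 and 2 adjusted over the list alone), ZNF841 by −1.47 ± 0.14. By camera the list had an adjusted p of 0.000496, and adjusted p = 0.336 with an estimated correlation. FAR2P1, at 22.4 ± 3.00 CPM in WT, had no count in KO and was at least 318.5-fold lower. POTEF had a ratio of 0.00143 (95% counting interval 0.000173 to 0.00517). PUS7L, an RNA-modifying enzyme gene, also had no count in KO and was at least 285.4-fold lower, and ZNF300 fell by 4.64 ± 0.23. LRRC61, PNPLA4 and ZBED10P had no count in WT and were at least 144.3-fold, 103.5-fold and 67.4-fold higher in KO. H1-1, a linker histone, had a ratio of 197.5 (95% counting interval 67.3 to 960) and MAGEH1, on the X chromosome, one of 267 (73.7 to 2210). Of 520 X-linked genes tested 40 were higher (Fisher's exact test, adjusted p = 4.9e-28) and 8 lower. In the 19p12 cluster ZNF737 rose from 0.264 ± 0.148 to 7.63 ± 2.26 CPM while ZNF506 (−3.63 ± 0.29) and ZNF66 (−1.02 ± 0.10) fell, of 26 tested. The list had a camera adjusted p of 0.00193, and adjusted p = 0.414 with an estimated correlation. Among cell type markers, the dorsal gene ZIC1 fell from 40.7 ± 2.58 to 11.8 ± 3.84 CPM (−1.78 ± 0.16) and the neural crest gene PAX7 from 8.13 ± 3.06 to 1.73 ± 1.14 (−2.28 ± 0.40), and PMEL, a pigment cell gene, rose from 79.6 ± 8.22 to 114 ± 5.85. Of the 6 midbrain and hindbrain markers 2 fell, of 18 telencephalic markers 3 rose, of 13 neuron markers none passed (4 rose adjusted over the list alone), and of 23 progenitor markers 2 fell. Single libraries ended several of these calls. Leaving out 1 library gave an adjusted p of up to 0.132 for PAX8 and 0.140 for IRX2 (the midbrain and hindbrain markers), 0.1405 for FEZF1, 0.126 for NR2F1 and 0.0624 for NR2F2 (the telencephalic markers) and 0.0703 for FABP7 (progenitors). For DNMT3B (pluripotent and 20q11.21), KDR (endothelial) and ZNF433 (19p13.2), which also passed with all 8 libraries, it gave up to 0.174, 0.0588 and 0.115. FEZF1 and DNMT3B lost their calls whichever of the 8 libraries was left out. Beta protocadherins fell in 1 of 9 (PCDHB2, adjusted p of up to 0.0626 without 1 library), with a camera adjusted p of 7.5e-05 and adjusted p = 0.0642 with an estimated correlation. In p53 targets 1 of 23 rose (PHLDA3, lost whichever of the 8 libraries was left out, adjusted p of up to 0.1496), with a camera adjusted p of 0.00548, and adjusted p = 0.336 with an estimated correlation. No gene of the cell cycle (30), cholesterol synthesis (22), stress response (24), interferon (15) or imprinted (22) lists passed, and in the WNT (14) and hypoxia (23) lists 2 genes each rose adjusted over the list alone. In all, 113 genes were higher and 126 lower of 14887 tested. With the replicate number as a block the counts were 252 and 295, although KO replicates 2 and 4 correlated best with a WT library of another number. Replicates 1 and 2 also differed from 3 and 4 in both genotypes, and with these sets as the block the counts were 277 and 302. With no filter on low counts there were 558 calls, and 137 at an adjusted p of 0.01.

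**Figure D3:**
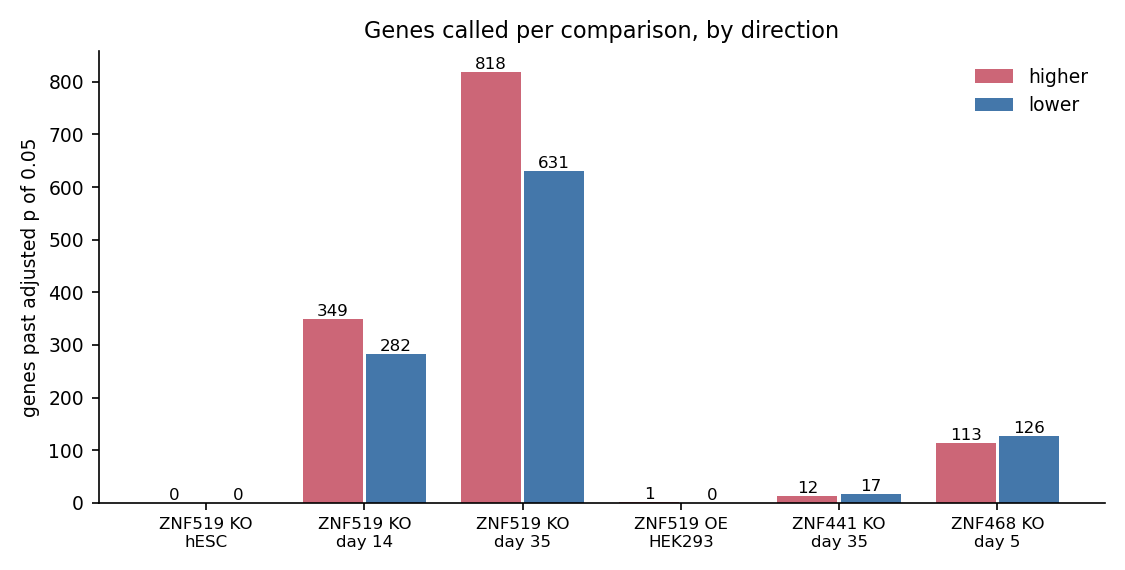
Number of genes past an edgeR adjusted p of 0.05 in each comparison, with genes higher in KO or OE in red and lower in blue. Counts run from 0 in hESC to 818 higher and 631 lower in ZNF519 KO organoids of day 35.

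The genes called in 1 comparison were then set against those of others that share no library, with Fisher's exact test (two-sided) over the genes tested in both. ZNF519 KO organoids of day 14 and day 35 shared 116 lower genes where independence would give 10.6 (adjusted p = 6.9e-91) and 65 higher genes against 16.1 (adjusted p = 6.9e-22), and both ages came from the same 2 clones. The ZNF468 knockout at day 5 shared 31 lower genes with ZNF519 KO at day 14 (1.90 by independence, adjusted p = 3.0e-28) and 38 with day 35 (4.14 by independence, adjusted p = 5.0e-26). FAR2P1, CAT and CFLAR, a regulator of caspase-8, were lower in all 3. The ZNF441 knockout shared 6 lower genes with ZNF519 KO at day 35, including PPP1R3C and ZNF772 (adjusted p = 1.3e-05), and 4 higher genes, CHCHD2, FAM131A, FOS and NPAS4 (adjusted p = 0.00453). Between these 2 knockouts 5 genes moved in opposite directions. CAT and TGFA were higher in the ZNF441 KO and lower in the ZNF519 KO, and CYP2R1, SMPD3 and ZNF680 the reverse (3 against 0.650 by independence, adjusted p = 0.0445). Opposite directions were also found between the ZNF468 KO and day 14, with 7 genes higher in the former and lower in the latter (1.69 by independence, adjusted p = 0.00360), ZNF559 and ZNF737 among them. FOS was higher in the ZNF468 KO as well (15.7 ± 1.35 against 10.96 ± 1.34 CPM, adjusted p = 0.0492), only just past the test, so FOS was higher in 3 knockouts. Higher genes of the ZNF468 KO were shared with day 14 (9 against 2.26 by independence, adjusted p = 0.00116), and with day 35 there were 8 against 5.18 (adjusted p = 0.2999). The ZNF468 and ZNF441 knockouts shared 4 lower genes, PPP1R3C and ZNF585B among them (0.0926 by independence, adjusted p = 8.2e-06), while 3 genes, ZNF737 among them, were higher in the former and lower in the latter (0.105 by independence, adjusted p = 0.000483). HEK293 overexpression shared only ZNF519, its single called gene, with the knockout organoids. These shared genes, apart from ZNF519, are named as the tables list them and were chosen after their values were seen.

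**Figure D4:**
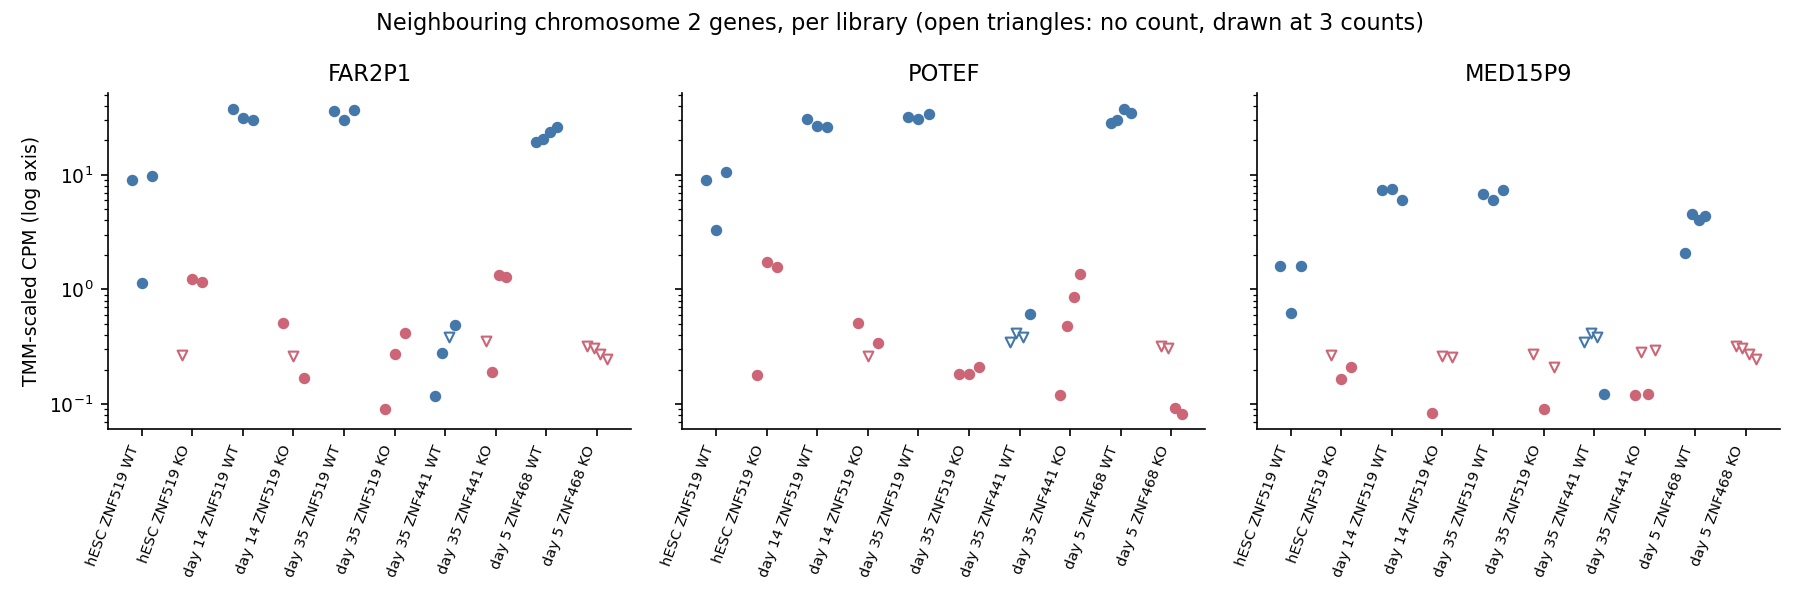
FAR2P1, POTEF and MED15P9 in each hESC and organoid library, in TMM-scaled CPM on a log axis, with WT in blue and KO in red; open triangles mark libraries with no count, drawn at 3 counts, and the 3 count tables were scaled separately. The genes are low in ZNF519 KO and ZNF468 KO organoids, and also in the WT organoids of the ZNF441 experiment, where POTEF is at 0.153 ± 0.306 CPM.

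H3K4me3 in day 35 organoids was compared by the presence of peaks. The 3 WT libraries listed 37871, 35924 and 35908 peaks and the 3 ZNF519 KO libraries 40492, 38195 and 41620. KO libraries had more peaks (40102 ± 1745 against 36568 ± 1129, SD, n = 3) that were shorter (median length 397 ± 42.3 against 527 ± 18.9 bp) and covered less sequence (20.9 ± 0.559 against 22.5 ± 0.215 Mb). Of peaks with a −log10 q of at least 5 the KO libraries had 33728, 31531 and 31522 and the WT libraries 32695, 31852 and 31994, so the KO excess was not seen among them. The median summit fold was 5.68, 5.02 and 4.94 in KO and 6.27, 6.21 and 6.16 in WT libraries. The number, length and coverage of all peaks had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Merging peaks of all libraries gave 46948 regions, of which 24504 (52.2%) had a peak in all 6 libraries. There were 571 regions with a peak in all 3 WT and no KO library and 280 with the reverse. Of regions found in either library, KO replicate 1 shared 79.4%, 81.5% and 82.2% with WT replicates 1, 2 and 3. With KO replicates 2 and 3 it shared 74.9% and 67.1%, so it resembled the WT libraries more than the other KO libraries. With WT replicates 1 and 2 and KO replicate 1 against the rest, 464 regions were specific to a side. The longest found in WT alone were on chromosome 17 at 20771822 to 20773158, chromosome 4 at 188426053 to 188427225, chromosome 17 at 80187046 to 80188109 and chromosome 19 at 56879401 to 56880429 (hg19). The longest found in KO alone were on chromosome 7 at 8010961 to 8012096, chromosome 11 at 101917981 to 101918881, chromosome 3 at 181432230 to 181433107 and chromosome 9 at 42804443 to 42805253. Genotype-specific regions were short, with median lengths of 329 bp (WT) and 264.5 bp (KO) against 953 bp for regions found in all 6 libraries. The regions were not matched to genes, since no hg19 annotation was used here. The WT-only count was 871 without WT replicate 2, 1027 without WT replicate 3 and 2389 without KO replicate 1, and the KO-only count was 1177, 458 and 475 without KO replicates 1, 2 and 3. With a library left out fewer libraries must hold or lack a peak, so a rise is built in. With the same number of peaks per library the counts were 951 and 178, with peaks up to 500 bp apart merged they were 283 and 163, and where peaks had to cover at least 0.5 of the region there were 1117 WT-only regions.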

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

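Tests chosen after the result was seen are those on clones with genes changed at least 2-fold, on the share of neurons, on neighbouring genes, on a common target set and on H3K4me3 splits. Dixon's test marked 10 of 116 groups of 4 libraries as having a library far from the other 3, and chance does so in about 1 in 20 groups. In the ZNF441 experiment PPP1R3C was at 5.01 CPM in WT replicate 4 (others 3.46 to 3.59), ZNF585B at 26.6 in WT replicate 2 (21.0 to 21.2), ZNF596 at 0.257 in WT replicate 3 (others 0) and ZNF737 at 75.2 in KO replicate 1 (57.2 to 60.2). In the ZNF468 experiment MAGEH1 was at 0.241 CPM in WT replicate 4 (others 0), PAX8 at 40.4 in KO replicate 3 (12.9 to 17), PMEL at 67.3 in WT replicate 2 (82.8 to 84.6) and ZNF841 at 13.5 in WT replicate 4 (15.2 to 15.5). ZIC1 was at 17.5 CPM in KO replicate 3 (9.41 to 10.4) and at 44.5 in WT replicate 4 (39.2 to 39.6).

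Of the 6 genes past the interaction test for day 35 against day 14, those named by the rule were FOS (2.95), NPAS4 (2.95), NR4A1 (1.76) and SLC7A8 (1.198). For day 35 against hESC, stage changes together with the clones (1 per genotype in organoids and 3 in hESC). Of the 19 genes past that test, those named were FOSB (3.78), FOS (3.17), NR4A1 (2.31), SLC7A8 (1.48), HHLA1 (−3.55), ZNF132 (−4.52), ZNF772 (−4.62) and ZFP28 (−5.56). Clone 31 was below clone 7 in hESC already for the last 3.

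A pattern to weigh is that 161 genes with hESC values were called in the same direction at day 14 and day 35 of the ZNF519 knockout, where KO means clone 31 and WT clone 7. Directions, medians and quartiles in hESC were read against the single library of WT clone 2. Among the 27 changed at least 2-fold, 8 and 9 had the organoid direction in hESC in KO clones 92 and 93 (higher median −0.311) and 24 in clone 31 (median 0.935). These are the values that a difference of clone 31 needs. The upper quartiles of clones 92 and 93, at most 0.22, show that these genes as a set did not shift there as in clone 31. This does not decide on loss of ZNF519 acting already in hESC, since clones 92 and 93 kept 67 and 17 ZNF519 counts, against 5 in clone 31. In CPM, ZNF519 was at 0.446, 5.54 and 1.78 in clones 31, 92 and 93. It was at 39.0, 11.1 and 45.8 in WT clones 2, 6 and 7. Single genes differed, as FAR2P1 was at 1.14 and 1.06 CPM in clones 92 and 93 and at 8.19, 1.08 and 8.98 in WT clones 2, 6 and 7. A difference of WT clone 7 (−0.224, quartiles −0.77 to 0.036) cannot be told apart, nor, over all 161 genes, can clone 31 (−0.097) or clone 7 (−0.076), since small effects are within the spread of the clones. Loss of ZNF519 acting only in organoids was not tested, because all organoids came from 1 clone per genotype.

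The rise of FOS, NPAS4, FOSB and NR4A1 at day 35, a group named after their values were seen, was weighed against the share of neurons and stress at harvest. A larger share of neurons as a whole is argued against by the median of 21 neuron markers, −0.031 with an interquartile range of 0.295, beside 2.86 for FOS. This median does not address a change in a subtype or in the activity of neurons, which was not tested. Stress of handling cannot be told apart, since the 12 heat shock and stress genes had a median of 0.149 and 4 of them rose. Of these 4, HSPA8 (0.413 ± 0.054) and HSPH1 (0.295 ± 0.052) also rose at day 14, and HSPD1 and HSP90AA1 did not pass there. FOS was then at 6.93 CPM in KO and 7.27 in WT, so a rise of heat shock genes alone did not come with one of FOS. The order of harvest is not in the labels, and FOS also rose in the ZNF441 and ZNF468 knockouts. Loss of ZNF519 as the biological explanation remains untested, with 1 clone per genotype.

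Large changes recurred in knockouts of different zinc finger genes, as FAR2P1, POTEF and MED15P9 did for ZNF519 and ZNF468. At day 35, 7 genes changed at least 2-fold lay beside a gene changed the same way. In a permutation test of gene order the permuted 95% limit was 2 (one-sided p = 1.0e-04, the smallest possible). These 7 genes were FAR2P1, POTEF and MED15P9, the genes of the pattern itself, ZIC5 and ZIC2, and CCDC144NL and CCDC144NL-AS1. The counts were 9 at day 14, 24 for ZNF468 and 2 for ZNF441 (permutation test, p = 0.0048). Those for ZNF468 include the deleted gene and its neighbour ZNF28. Neighbours controlled together would also exceed shuffled order, so the test cannot decide on silencing or activation of neighbours that differs between clones. A common target set of the deleted proteins cannot be told apart, as 0 of 7 genes changed at least 4-fold in the ZNF519 and ZNF468 knockouts moved in opposite directions. The 3 neighbours were under 1 CPM already in WT organoids of the ZNF441 experiment.

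Other splits of the same libraries were counted for each result. With 10 splits there are too few for a share under 0.05. There, hESC had 0 calls and 10 of 10 splits had as many (highest other 0), day 14 had 631 (highest other 1), day 35 had 1449 (0), HEK293 had 1 (0), WT day 35 against day 14 had 13580 (0) and H3K4me3 had 851 regions (464), each of the last 5 reached by 1 split. For ZNF441 1 of 35 splits reached 29 (highest other 21), a share under 0.05 over all splits. That excludes chance only if libraries of equal number are not pairs, which is not known. It does not exclude a difference in clones, which the titles do not name. The split with 21 was replicates 1 and 2 against 3 and 4, and of the 8 splits that part equal numbers only the real one reached 29 (highest other 0), too few for a share under 0.05. For day 35 against hESC 1 of 60 splits reached 19 (highest other 7). These splits shuffle genotype within every stage, so they also remove any knockout effect that the stages share. They therefore cannot exclude chance for a difference of that effect between stages. A difference in clones is not excluded either, since the splits move libraries and organoids hold 1 clone per genotype. For ZNF468 2 of 35 splits reached 239, the other being replicates 1 and 2 against 3 and 4 with 1482, a structure of the samples. Of the 8 splits that part equal ZNF468 numbers only the real one reached 239 (highest other 0), too few for a share under 0.05. With the replicate block there were 547 calls. Chance cannot be excluded for day 35 against day 14, where 4 of 60 splits reached 6 (highest other 7).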

How the results depend on the processing

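Alternatives added after seeing the data were the ZNF468 block of replicates 1 and 2 against 3 and 4 and the HEK293 fit without 2 libraries. Of 6044 values of named genes under alternatives, 5580 stayed on their side of the threshold, and 0 turned with a call in either fit. A change of direction between values that were not called was not counted as turning. Of 3186 list values 2949 stayed on their side, and 2 turned. Those 2 were pluripotent markers in HEK293 with no filter (−1.284, adjusted p = 0.00282) and retina and pigment markers of WT organoids with fry (median −1.778, adjusted p = 0.000213, where fry pointed up). Of 49 list calls by camera 0 remained with an estimated correlation. Fry made 36 calls, with 28 lists losing a call, 14 gaining one and 1 turned. Overlap tests that passed numbered 14 at 0.05 and 12 at 0.01, in part for other pairs, with ZNF519 itself among them. Lower genes shared by the ZNF441 and ZNF468 knockouts went from 4 to 0, while the ZNF468 KO still shared 24 with day 35. Those of the ZNF441 KO and day 35 went from 6 to 1 (Fisher's exact test, adjusted p = 0.199). Higher genes of the ZNF468 KO and day 14 went from 9 to 1 (Fisher's exact test, adjusted p = 0.638).

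Counts of genes were, for hESC, 8 with DESeq2, 5 in the joint fit and 0 to 14 leaving out 1 library. For day 14 they were 311 at 0.01, 368 with DESeq2, 997 with a replicate block, 40 in the joint fit and 323 to 771 leaving out 1 library. For day 35 they were 593 at 0.01, 733 with DESeq2, 48 in the joint fit and 667 to 1588 leaving out 1 library. HEK293 had 116 with no filter, 14 with DESeq2, 20 without 2 libraries and 1 to 33 leaving out 1. ZNF441 had 155 with no filter, 45 with DESeq2, 50 with a replicate block and 24 to 33 leaving out 1 library. Each ZNF441 library correlated best with its own number (0.133, 0.109, 0.049 and 0.229), a hint from the data and not the design. ZNF468 had 558 with no filter, 137 at 0.01, 547 with a replicate block, 579 with replicates 1 and 2 against 3 and 4 as the block and 160 to 257 leaving out 1 library. WT day 35 against day 14 had 13098 to 13656 leaving out 1 library. Day 35 against day 14 had 12 with no filter, 1 at 0.01, 423 with a replicate block and 1 to 130 leaving out 1 library. Day 35 against hESC had 45 with no filter, 4 at 0.01 and 6 to 477 leaving out 1 library. A threshold of 0.01 lowers a count by construction. Leaving out a library lowered some counts and raised others, and for these and the rest the cause was not tested.

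H3K4me3 regions in KO only were 178 with equal numbers of peaks, 163 with merging within 500 bp and 368 to 1177 leaving out 1 library. Those in WT only were 951, 283 and 654 to 2389, and 1117 when peaks had to cover at least 0.5 of the region. A rise is built in when a library is left out, since fewer libraries must then hold or lack a peak. For the other settings the cause was not tested. No paired analysis was possible because hESC numbers name clones and the counts of H3K4me3 regions come from no test, and the H3K4me3 measures per library were not tested by number. The test of H3K4me3 regions against RNA was not run. In simulated data 0 of 67 changes of 2-fold were found in hESC, and 58.2% in HEK293. In the interactions 10.4% were found against day 14 and 11.9% against hESC.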

Other observations

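Genes of chromosome 19, which holds most KRAB zinc finger genes, were over-represented among lower genes in all 4 organoid knockout comparisons (Fisher's exact test), with the deleted genes ZNF441 and ZNF468, and ZNF28 beside ZNF468, counted in their own knockouts. Of the genes tested there, 43 of 993 were lower at day 14 (adjusted p = 3.9e-07), 59 of 995 at day 35 (adjusted p = 0.00310), 7 of 938 in the ZNF441 knockout (adjusted p = 0.000183) and 17 in the ZNF468 knockout (adjusted p = 0.0320). Day 14 and day 35 hold the same clones, so these comparisons are not independent. At day 35 higher genes were over-represented on chromosomes 4, 5 and X (Fisher's exact test, each adjusted p = 0.00310). In hESC, ZFP28 was at 0.244 CPM in KO clone 31 and at 6.74 and 7.40 in KO clones 92 and 93, against 3.26, 4.20 and 3.89 in WT clones 2, 6 and 7. CCDC144NL-AS1 was at 1.87 CPM in clone 31 and at 36.6 and 16.1 in clones 92 and 93. ZNF542P was at 0.0815 CPM in clone 31 and at 10.6 and 3.85 in clones 92 and 93. Levels of some other genes, picked after they were seen and not past the test in hESC, were as follows. HHLA1 was at 43.3, 51.4 and 65.6 CPM in clones 31, 92 and 93 and at 9.49, 11.24 and 16.6 in WT clones 2, 6 and 7. ZNF680 was at 25.8, 39.7 and 35.9 CPM in these KO clones and at 11.01, 8.501 and 16.2 in WT. POTEF was at 0.163, 1.59 and 1.44 CPM in the KO clones and at 8.26, 3.13 and 9.68 in WT.

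In WT organoids RPE65, an enzyme of the visual cycle, had no count at day 14 and 5.44 ± 0.610 CPM at day 35 (n = 3), at least 67.0-fold higher. The intermediate filament gene NES fell from 782 ± 26.3 to 187 ± 3.32 CPM and RSPO1, a WNT agonist of the cortical hem, from 18.1 ± 2.78 to 0.343 ± 0.177.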
